A study of Homo sapiens with 9 samples.

How the data were processed

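The deposited values are counts of reads per gene, 1 file per library, that the submitters made with STAR 2.7.10a and HTSeq on hg38 after FastQC, per the submitters' processing notes. The counting strand setting and the annotation release are not given in the sources used here, so genes that overlap on opposite strands are uncertain. The labels conflict on the library: the molecule is given as polyA RNA, while the protocol text describes ribosomal depletion of total RNA and a kit for fixed tissue. The series text also gives a lower dose, which was not analysed here, and a further incubation after treatment, and the labels do not say whether it applies to these libraries. The 5 closing HTSeq totals of each file were left out of the genes and used only as depth measures. Every file had a group in the labels, with 3 libraries in each of the 3 groups, and no file was without one.

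Of 62703 gene identifiers, 62686 had a symbol in the reference table and 58264 a type and position in GENCODE 29. A symbol shared by several identifiers was kept on the identifier with the most counts. Genes were kept with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 quasi-likelihood (robust, a mean per group over 9 libraries; biological coefficient of variation 0.0529), in R 4.3.3. The SE of a log2 change is its size divided by the square root of the F statistic. Adjusted p-values are Benjamini-Hochberg over the genes tested in each comparison, at 0.05. CPM values use the TMM-scaled library sizes. Of 32 gene lists and 4 cell marker lists, all 960 symbols were matched. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, correlation 0.01, at least 5 genes tested), adjusted over the 32 lists, and again with an estimated correlation and with fry. The groups, the lists, the comparisons, the main test and the alternatives named below as fixed then were set before the data were examined.

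Named genes follow a rule: protein-coding, adjusted p under 0.05, mean of at least 5 CPM and no overlap between the libraries of the groups. From these the 6 largest and 6 smallest log2 changes and the 4 higher and 4 lower genes with the smallest p-values were taken against control, and 5 and 5 by fold between the doses. The 9 sphingolipid genes and up to 4 members per called list were named as well, and genes outside the rule are said to have been chosen after their values were seen. The text gives a part of those taken by the rule, and some items are withheld for evaluations.

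The alternatives fixed then were median-ratio and upper-quartile size factors, DESeq2 1.42.0, limma voom, no low-count filter, at least 50 counts on average, nuclear protein-coding genes only, only the groups compared in the fit, a block for the replicate number, a change of at least 1 log2 unit, each library left out in turn, and the other list tests. Library size alone, removal of the 50 most abundant genes, a covariate for 3 libraries that deviate together and a fit without those 3 were added after the data were seen. Over the genes changed in both comparisons with control, unchanged groups that share controls were simulated in 20 draws (seed 20).

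The test was also checked on simulated data with 200 genes changed and 10 draws (seed 7). Gene means over all 9 libraries and gene-wise dispersions of the joint fit were used for every comparison, so the comparisons are not separate checks. This check was written after the counts had first been fitted. At log2 changes of 0.25, 0.5, 1 and 2, edgeR recovered 32.0%, 55.9%, 75.4% and 92.8% of changed genes for 20 µM against control, 31.5%, 56.1%, 75.9% and 92.4% for 30 µM against control, and 31.1%, 55.9%, 77.1% and 93.8% between the doses. False calls made up 7.96%, 7.40% and 8.30% of calls (3.57% to 12.7% in single draws), above the 5% aimed at. With trended dispersions, a version added after that rate was seen, they made up 6.05%, 4.48% and 5.61%. Recovery and the false share depend on how many genes change. Only 200 changed in a draw, against 6020, 10707 and 10041 called in the data, so these rates do not carry over to those calls. Both lists moved in the simulation were called and 0 others, with either camera correlation. Each gene was drawn independently, so members of a list did not vary together in the simulation. In the data the estimated correlation reached 0.692, for mitochondrially encoded mRNAs. The simulation therefore cannot show how often camera calls such lists falsely.

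The 4 marker lists were only described, not tested. Splicing, the reads themselves, variants, and pathway collections other than the fixed lists were not analysed here.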

Results

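HepG2, a human hepatocellular carcinoma line, was left untreated or given eliglustat, an inhibitor of glucosylceramide synthase (the enzyme encoded by UGCG), at 20 or 30 µM for 72 h. The labels give no time for the controls. RNA sequencing gave 3 libraries per group, and each file held counts of reads per gene. The libraries held 21103757 to 26782810 counts in genes, and between 40.6% and 44.0% of records fell in no single gene. Of 62703 genes listed, 17623 had enough counts to be tested, and these held 99.9% of the counts in genes. Values for a gene are CPM (counts relative to the scaled library total) as mean ± SD over n = 3 libraries. Fold changes are log2 ± SE from edgeR quasi-likelihood with TMM scaling over all 9 libraries. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene is said to have changed only where the value was under 0.05. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No pair of libraries in a group agreed within sampling noise (chi-square per gene 2.07 to 7.80), so each was counted as a sample.

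The groups separated along the first component of log2 CPM, which held 60.9% of the variance, against 10.3% for the second. The number of genes past the test was 6020 at 20 µM against control, 10707 at 30 µM against control and 10041 at 30 µM against 20 µM. Replication-dependent histone genes took 0.464 ± 0.0145% of counts in controls, 0.337 ± 0.0156% at 20 µM and 0.163 ± 0.00404% at 30 µM (SD, n = 3). Mitochondrially encoded mRNAs took 3.43 ± 0.512%, 3.66 ± 0.176% and 5.40 ± 0.330% (SD, n = 3). For 30 µM against control the latter gave p = 0.1 and for 20 µM against control p = 0.5 in a two-sided exact permutation test, in which 0.1 is the smallest value that 3 against 3 libraries allow.

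**Figure D1:**
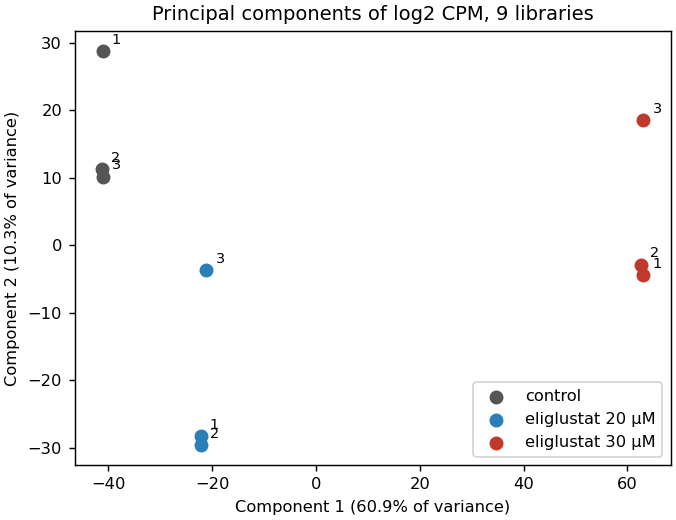
Principal components of log2 CPM for the 9 libraries, with component 1 (60.9% of variance) on the x axis, component 2 (10.3%) on the y axis, points for libraries numbered by replicate, and colours for groups. The 3 groups sit apart along component 1.

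At 20 µM, the gene for the drug's target rose: UGCG, which makes glucosylceramide from ceramide, was at 43.2 ± 2.90 CPM against 23.7 ± 1.51 in controls (SD, n = 3), a log2 change of 0.87 ± 0.0595, or 1.83-fold (adjusted p = 1.70e-13). B4GALT5, a lactosylceramide synthase and the next enzyme of the pathway, rose 1.77-fold from 123 ± 2.6 to 218 ± 0.454 CPM (log2 0.83 ± 0.0336, adjusted p = 4.77e-19). Of 48 cell cycle genes, 44 fell and none rose. In contrast, 19 of 24 cholesterol synthesis genes and 16 of 18 lysosomal sphingolipid breakdown genes rose and none fell. IGFBP1, a liver-secreted protein that binds insulin-like growth factors, had the largest rise among genes of at least 5 CPM, 7.91-fold from 9.33 ± 3.97 to 74.7 ± 2.67 CPM (log2 2.98 ± 0.217, adjusted p = 5.74e-05).

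In all, 3038 genes rose and 2982 fell at 20 µM against control, 34.2% of those tested, and 309 of them changed by at least 1 log2 unit (245 rose and 64 fell). In 5777 of the 6020 genes every treated library lay on the same side of every control library, which held for 44.5% of all genes tested against 10% by chance. After IGFBP1 came DEPP1, an autophagy regulator, which rose 4.24-fold to 50.9 ± 2.63 from 11.98 ± 0.592 CPM (adjusted p = 8.89e-24). FOS, an immediate early transcription factor (log2 1.94), TCP11L2, a gene of little described function (1.84), KLHL24, a ubiquitin ligase adaptor (1.84), and AQP3, a water and glycerol channel (1.84), followed. Among the genes with the smallest p-values, TP53INP1, a p53-induced autophagy gene, rose 2.56-fold from 35.3 ± 0.951 to 90.3 ± 0.316 CPM (adjusted p = 3.48e-20). The largest falls by the same rule were in metal-binding metallothioneins: MT1E fell by 1.79 log2 units (49.8 ± 5.66 to 14.4 ± 1.54 CPM) and MT1G by 1.78, both genes with near-identical copies whose counts are uncertain. NOTCH1, a receptor for signals between neighbouring cells, fell 2.24-fold from 16.3 ± 1.30 to 7.27 ± 0.596 CPM (adjusted p = 3.64e-10), and its target HEY1, a transcriptional repressor, fell by 1.29 log2 units. SLC2A3, a glucose transporter, fell by 1.10 and the metallothionein MT1F, also uncertain, by 1.05.

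Among the other sphingolipid genes followed at every dose, B4GALT6, the other lactosylceramide synthase, was not past the test (19.7 ± 0.865 against 18.1 ± 1.33 CPM, adjusted p = 0.224). ST3GAL5, which makes the ganglioside GM3, had 1.04 ± 0.351 against 0.503 ± 0.163 CPM (log2 1.02 ± 0.394, adjusted p = 0.0422). This call was lost without control 2 (0.160), control 3 (0.125), 20 µM library 1 (0.12) or 20 µM library 2 (0.204), with DESeq2 (0.0832), limma voom (0.0638) or no low-count filter (0.0548). GAL3ST1, the sulfotransferase that makes sulfatide from galactosylceramide, was not past the test (15.2 ± 0.636 against 13.6 ± 0.276 CPM, adjusted p = 0.154). ARSA, the lysosomal sulfatase that degrades sulfatide, rose 1.49-fold from 15.0 ± 0.727 to 22.3 ± 1.77 CPM (log2 0.57 ± 0.0811, adjusted p = 7.99e-07). UGT8, the galactosylceramide synthase, and GALC, the galactosylceramidase, had at most 1 and at most 2 counts in any library and were not tested. Counts near 0 may depend on the unstated annotation: INSIG1, a sterol-regulated gene named after its value was seen, was listed at 0 in all 9 libraries. On GRCh38 (GENCODE 29), UGCG lies at chromosome 9: 111896766-111935369 and B4GALT5 at chromosome 20: 49632945-49713878. GAL3ST1 lies at chromosome 22: 30554635-30574587, ARSA at chromosome 22: 50622754-50628173 and IGFBP1 at chromosome 7: 45888357-45893668.

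**Figure D2:**
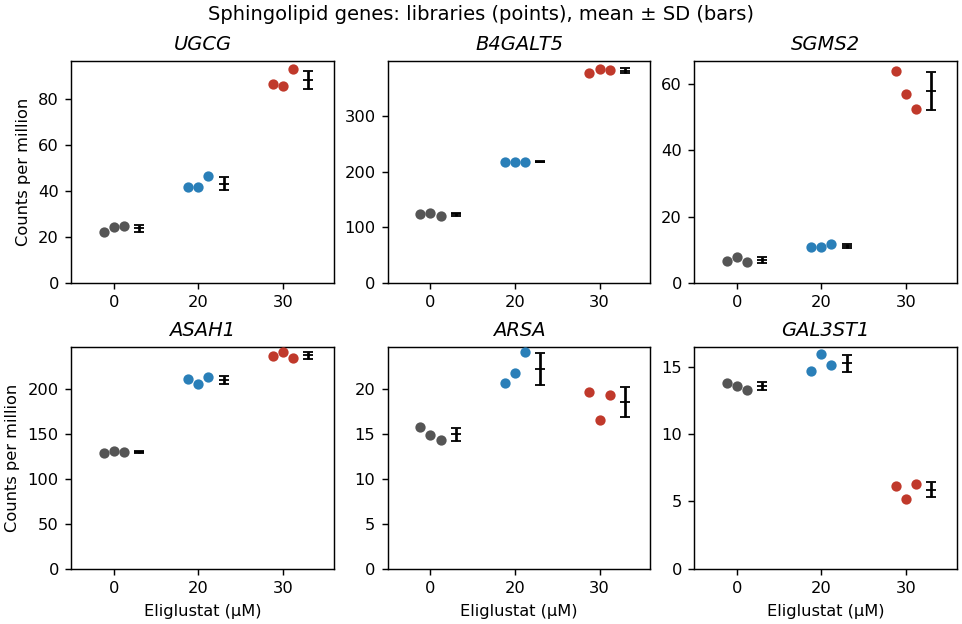
CPM (y axis) of UGCG, B4GALT5, SGMS2, ASAH1, ARSA and GAL3ST1 at 0, 20 and 30 µM eliglustat (x axis), with points for libraries and bars for mean ± SD (n = 3). UGCG went from 23.7 to 43.2 and 88.6 CPM, while GAL3ST1 went from 13.6 to 15.2 and 5.88 CPM.

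The 32 lists of genes were fixed before the data were examined and compared with all other genes by camera (correlation 0.01). At this dose 23 of them differed from other genes against control, 18 upward and 5 downward. Every count of genes past the test is followed, where it differs, by the count adjusted over the list alone. Of those 23 calls, 9 were kept with an estimated correlation: ceramide and sphingomyelin, lysosomal sphingolipid breakdown, lysosome, autophagy, cholesterol, fatty acid synthesis, phospholipidosis, cell cycle and NF-kB.

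In the sphingolipid lists, 5 of 16 glycosphingolipid synthesis genes rose, 1 fell and 10 were not past the test (median log2 0.11, camera adjusted p = 0.0416). The sialyltransferase ST3GAL1 rose by log2 0.18, and the faller, named after its value was seen, was B3GALT5, a galactosyltransferase, at 0.0275 against 0.198 CPM (log2 -2.65). That list's call was lost with an estimated correlation (adjusted p = 0.125), among nuclear protein-coding genes only (0.0555) and without control 1 (0.0622, median 0.07), control 3 (0.0655), 20 µM library 2 (0.0566) or 20 µM library 3 (0.0654). It was also lost without 3 libraries that deviate together, control 1, 20 µM library 3 and 30 µM library 3 (0.0782). Of 14 sulfatide and sulfation genes, 6 rose (7 adjusted over the list alone) and 1 fell, with median 0.17 and camera adjusted p = 0.00537 (adjusted p = 0.0808 with an estimated correlation). Among the rises were PSAP, the saposin precursor (0.40), and the sulfate carriers SLC26A1 (0.35) and SLC26A2 (0.49). Of 30 ceramide and sphingomyelin genes, 15 rose (16 adjusted over the list alone) and 3 fell (median 0.16, camera adjusted p = 0.000868). CERT1, the ceramide transporter (0.80), CERS4, a ceramide synthase (0.77), SGMS2, a sphingomyelin synthase (0.70), and SPTLC2, of the first step of the pathway (0.65), rose. Of 18 lysosomal sphingolipid breakdown genes, 16 rose, with median 0.36 and camera adjusted p = 1.45e-09, including the ceramidase ASAH1 (0.69) and the sialidase NEU1 (0.66).

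Lysosomal and lipid lists moved upward. Of 38 lysosome genes, 26 rose (27 adjusted over the list alone) and 2 fell (median 0.24, camera adjusted p = 6.93e-07). The peptidase TPP1 (0.71), the chloride transporter CLCN7 (0.60) and the protease CTSD (0.57) were among the rises. Of 29 autophagy genes, 18 rose and 1 fell (median 0.21, camera adjusted p = 4.66e-06). Rises were found in the LC3 relative GABARAPL1 (1.36) and the cargo receptors OPTN (1.25) and SQSTM1 (0.77). All 19 of the 24 cholesterol synthesis and uptake genes past the test rose (21 adjusted over the list alone), with median 0.42 and camera adjusted p = 5.28e-12. These included the sterol enzymes TM7SF2 (0.68) and LSS (0.59). Of 24 fatty acid and triglyceride synthesis genes, 18 rose and none fell (18 and 2 adjusted over the list alone), with median 0.32 and camera adjusted p = 5.34e-08. The phosphatase LPIN1 (1.06), the acetyl-CoA synthetase ACSS2 (0.87) and the fatty acid synthase FASN (0.65) rose. Of 9 phospholipidosis markers, 6 rose (7 adjusted over the list alone) and 2 fell (median 0.67, camera adjusted p = 0.00148). HPN, a liver serine protease, rose (0.70). Of 13 LXR targets, 8 rose and 1 fell, with camera adjusted p = 0.00941 (adjusted p = 0.125 with an estimated correlation). SMPDL3A, a phosphodiesterase (1.01), and ABCA1, a cholesterol exporter (0.18), rose. Of 25 fatty acid oxidation and PPARA targets, 11 rose and 4 fell, with CPT1A, of mitochondrial fatty acid import, at 0.81 (median 0.17, camera adjusted p = 0.0343). That call was lost with an estimated correlation (adjusted p = 0.245), among nuclear protein-coding genes only (0.0533) and without control 1 (0.0582), 20 µM library 3 (0.0654) or the 3 libraries that deviate together (0.111).

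Cell cycle genes had the lowest camera value (median log2 -0.58, adjusted p = 3.00e-26), with PLK1 (-0.77) and CCNB1 (-0.77) of mitosis and MCM4 (-0.60) of DNA replication among the 44 that fell. Of 27 histone genes, 22 fell (23 adjusted over the list alone), with median -0.45 and camera adjusted p = 5.28e-12 (adjusted p = 0.0769 with an estimated correlation). The histone genes H2AC4 (-0.85) and H1-5 (-0.78) fell, though histone genes have near-identical copies, so single members are uncertain. Of 18 heat shock genes, 11 fell (12 adjusted over the list alone) and none rose, with median -0.31 and camera adjusted p = 4.44e-06 (adjusted p = 0.0613 with an estimated correlation). The chaperones HSP90AA1 (-0.57) and HSPA8 (-0.46) were among them. Of 24 endoplasmic reticulum chaperones, 13 fell (14 adjusted over the list alone) and 5 rose (7), with camera adjusted p = 0.0302. CALR, a calcium-binding chaperone, was at -0.62 and HSPA5, or BiP, at -0.33. The list's call was lost with an estimated correlation (adjusted p = 0.394), among nuclear protein-coding genes only (0.0550) and without 20 µM library 2 (0.0539). Of 40 nuclear genes of oxidative phosphorylation, 15 fell and none rose, including UQCRC2 of complex III (-0.30), with median -0.11 and camera adjusted p = 0.00116 (adjusted p = 0.234 with an estimated correlation).

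Stress, signalling and liver lists made up the rest of the calls at 20 µM. Of 35 integrated stress response genes, 18 rose (19 adjusted over the list alone) and 4 fell, with camera adjusted p = 0.000176 (adjusted p = 0.0879 with an estimated correlation). The mTOR inhibitor DDIT4 (0.84) and the secreted stress cytokine GDF15 (0.81) were among the rises. Of 19 NF-kB genes, 12 rose and 1 fell, including the subunit RELB (1.62) and the inhibitor NFKBIA (0.44) (median 0.44, camera adjusted p = 7.42e-05). Of 26 immediate early and MAPK feedback genes, 16 rose and 1 fell, with median 0.29 (0.19 without 20 µM library 2) and camera adjusted p = 6.52e-07 (adjusted p = 0.0931 with an estimated correlation). EGR1 (1.68) and JUNB (1.34), both transcription factors, rose. Of 28 TGF-beta and matrix genes, 11 rose (13 adjusted over the list alone) and 3 fell, including SPARC, a secreted matrix protein (0.49), with median 0.08 and camera adjusted p = 0.0284. That call was lost with an estimated correlation (adjusted p = 0.394), without a low-count filter (0.0919) and without control 2 (0.0660), control 3 (0.0655), 20 µM library 3 (0.160, median 0.05) or the 3 libraries that deviate together (0.0876). Of 41 hepatocyte secreted proteins, 26 rose (27 adjusted over the list alone) and 6 fell, with camera adjusted p = 5.41e-05 (adjusted p = 0.156 with an estimated correlation). APOM of high-density lipoprotein (0.57) and complement C3 (0.49) rose. Albumin and alpha-fetoprotein, named after their values were seen, fell instead (ALB -0.32, AFP -0.38). Of 26 drug metabolism genes, 13 rose and 1 fell, including the cytochrome CYP3A5 (0.88), with camera adjusted p = 0.000436 (adjusted p = 0.0661 with an estimated correlation). Of 15 bile acid genes, 6 rose and 2 fell, including NR0B2, the FXR-induced repressor (0.97), with camera adjusted p = 0.0402. That call was lost with an estimated correlation (adjusted p = 0.234), among nuclear protein-coding genes only (0.0555) and without control 1 (0.0582), control 3 (0.0581), 20 µM library 3 (0.0952) or the 3 libraries that deviate together (0.111).

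The other 9 lists did not differ from other genes at 20 µM. NRF2 targets (12 rose and 6 fell of 26, 13 and 8 adjusted over the list alone), p53 targets (6 and 11 of 28, 9 and 11), glycolysis and hypoxia genes (12 and 9 of 34, 12 and 10) and Wnt targets (7 and 4 of 17, 7 and 5) held changes in both directions, with camera adjusted p = 0.196, 0.547, 0.814 and 0.194. Interferon genes (6 and 3 of 27), epithelial genes (8 and 5 of 24, 8 and 6) and apoptosis regulators (9 and 5 of 25, 11 and 5) gave camera adjusted p = 0.562, 0.857 and 0.205. Of 13 mitochondrially encoded mRNAs 1 rose (camera adjusted p = 0.264, but 0.00676 without control 1 and 0.0128 without the 3 libraries that deviate together), and of 50 ribosomal protein genes 5 rose (4 adjusted over the list alone, camera adjusted p = 0.271). The p53 targets had median -0.06 with mean 0.03, and the epithelial genes median -0.04 with mean 0.01.

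At 30 µM against control, UGCG rose 3.75-fold to 88.6 ± 3.93 CPM (SD, n = 3; log2 1.91 ± 0.0576, adjusted p = 3.74e-24) and B4GALT5 3.10-fold to 382 ± 3.96 CPM (log2 1.63 ± 0.0337, adjusted p = 7.35e-29). All 48 cell cycle genes fell, 25 of 26 immediate early and MAPK feedback genes rose, and 25 of 29 autophagy genes rose. IGFBP1 rose 128-fold to 1211 ± 18.0 CPM (log2 7.0 ± 0.214, adjusted p = 1.44e-07). CXCL8, the neutrophil-attracting chemokine interleukin-8, rose 83.4-fold from 0.615 ± 0.301 to 49.8 ± 0.515 CPM (log2 6.38 ± 0.136, adjusted p = 3.77e-28). GAL3ST1, not past the test at the lower dose, fell 2.31-fold to 5.88 ± 0.592 CPM (log2 -1.21 ± 0.1, adjusted p = 1.77e-12).

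In total 5192 genes rose and 5515 fell, 60.8% of those tested, and 2822 changed by at least 1 log2 unit (1381 rose and 1441 fell). In 10330 of the 10707 genes the libraries of the groups did not overlap, as in 65.0% of all genes tested. Scaled by library size alone, a setting added after the data were seen, the split was 3530 higher and 8022 lower, and the median of all genes moved by -0.210. Of the scalings fixed before, upper-quartile factors gave 4636 higher and 6225 lower, and median-ratio factors 5425 and 5272. Next to IGFBP1 and CXCL8 in size of rise were RASD1, a Ras-related protein (4.90), DUSP5, a phosphatase of ERK (4.50), AQP3 (4.50) and METRNL, a secreted factor (4.46). Among the genes with small p-values, GDF15 rose 18.5-fold from 160 ± 8.29 to 2959 ± 88.9 CPM (log2 4.21 ± 0.0399, adjusted p = 1.59e-36). The largest falls were in SCN1A, a sodium channel, 8.99-fold from 33.2 ± 0.972 to 3.68 ± 0.469 CPM (adjusted p = 4.78e-23), NFE2, a transcription factor (log2 -3.16), MT1G (-2.82), KIRREL2, an adhesion protein (-2.71), and NOTCH1, 6.55-fold to 2.49 ± 0.493 CPM (adjusted p = 1.23e-18). CXCL8 lies at chromosome 4: 73740506-73743716 and GDF15 at chromosome 19: 18374731-18389176.

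B4GALT6 (19.8 ± 0.651 CPM, adjusted p = 0.139) and ST3GAL5 (0.344 ± 0.167 CPM, adjusted p = 0.301) were not past the edgeR test at 30 µM. ARSA rose by log2 0.31 ± 0.0827 to 18.5 ± 1.67 CPM (adjusted p = 0.00176), a call lost with library size alone (adjusted p = 0.309). SGMS2 rose 8.45-fold from 6.89 ± 0.867 to 57.9 ± 5.78 CPM (log2 3.08 ± 0.0845, adjusted p = 1.78e-24); it lies at chromosome 4: 107824563-107915047.

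Of the 32 lists, 20 differed at 30 µM against control, 17 upward and 3 downward. Only 6 of these calls were kept with an estimated correlation: autophagy, cholesterol, NRF2, cell cycle, NF-kB and immediate early genes. Counts adjusted over the list alone were the same except where given. Glycosphingolipid synthesis (7 rose and 2 fell of 16, median 0.26) gave camera adjusted p = 0.0488 (adjusted p = 0.122 with an estimated correlation). B4GALNT1, the GM2 synthase, rose (1.16). The list's call was lost without control 1 (0.0610), 30 µM library 1 (0.0621, median 0.45) or 30 µM library 2 (0.0621), with median-ratio size factors (0.0552) and among nuclear protein-coding genes only (0.0961). Its median was 0.05 with library size alone. Ceramide and sphingomyelin genes rose (18 and 7 fell of 30, median 0.36, camera adjusted p = 0.0112, and adjusted p = 0.0748 with an estimated correlation), with SPTLC2 (1.05) and CERT1 (1.00) among them. Lysosomal sphingolipid breakdown genes (14 rose and 3 fell of 18, median 0.51) gave camera adjusted p = 0.000604 (adjusted p = 0.122 with an estimated correlation) and included ASAH1 (0.87) and PSAP (0.69).

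Lysosome genes (28 rose and 5 fell of 38, median 0.49) gave camera adjusted p = 1.96e-06 (adjusted p = 0.0537 with an estimated correlation). The proteases CTSB (1.74) and CTSL (1.45) rose. Among autophagy genes (25 rose and 1 fell, median 0.62, camera adjusted p = 5.23e-08), GABARAPL1 rose 10.3-fold, SQSTM1 6.94-fold and the LC3 gene MAP1LC3B 3.52-fold. Cholesterol genes (17 rose and 2 fell of 24, median 0.40, camera adjusted p = 5.10e-05) included the reductase DHCR7 (log2 1.00) and the synthase HMGCS1 (0.76). Phospholipidosis markers (8 rose and 1 fell of 9, median 0.36) gave camera adjusted p = 0.00137 (adjusted p = 0.0527 with an estimated correlation), with TAGLN, an actin-binding protein, at 1.29. NRF2 targets (22 rose and 2 fell of 26, median 0.57, camera adjusted p = 3.05e-08) included GCLC, of glutathione synthesis (5.34-fold), and the thioredoxin reductase TXNRD1 (1.88). Integrated stress response genes (20 rose and 9 fell of 35, median 0.34) gave camera adjusted p = 0.00184 (adjusted p = 0.122 with an estimated correlation). Their transcription factor ATF3 (15.4-fold) and phosphatase subunit PPP1R15A (3.08) rose. Glycolysis and hypoxia genes (22 rose and 7 fell of 34, median 0.39) included the glucose transporter SLC2A1 (3.80-fold), with camera adjusted p = 0.00191 (adjusted p = 0.0764 with an estimated correlation).

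NF-kB genes (14 rose and 2 fell of 19, 14 and 3 adjusted over the list alone, median 1.14, camera adjusted p = 5.41e-05) included the adhesion receptor ICAM1 (4.81-fold) and the subunit NFKB2 (2.10). The immediate early and MAPK feedback list had the largest median, 2.98 (camera adjusted p = 3.53e-14), with the phosphatase DUSP1 (13.4-fold), the survival factor IER3 (12.7-fold) and the transcription factor KLF6 (12.3-fold). TGF-beta and matrix genes (23 rose and 3 fell of 28, median 0.89) gave camera adjusted p = 2.78e-07 (adjusted p = 0.0953 with an estimated correlation). CCN1, a matrix protein (3.74), and the integrin ITGA2 (3.21) rose. Apoptosis regulators (16 rose and 6 fell of 25) gave camera adjusted p = 0.00215 (adjusted p = 0.0953 with an estimated correlation). They included the survival factor MCL1 (4.43-fold) and BMF, which promotes cell death (1.42). Their median was 0.25, 0.39 without control 2 and 0.04 with library size alone. Epithelial genes (13 rose and 6 fell of 24, median 0.26) included the tight-junction gene CLDN4 (1.42) and the keratin KRT18 (0.99), with camera adjusted p = 0.0154 (adjusted p = 0.122 with an estimated correlation).

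Cell cycle genes fell by a median of 1.36 log2 units (camera adjusted p = 7.79e-22), including TYMS, of thymidylate synthesis (-1.52), and the replication helicase gene MCM3 (-1.44). Of 27 histone genes 26 fell (median -1.46, with H1-5 at -2.28), with camera adjusted p = 7.49e-12 (adjusted p = 0.0862 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell (3 rose and 21 fell of 40, median -0.18), with ATP5MC1 at -0.51, a subunit of ATP synthase, and camera adjusted p = 0.0112 (adjusted p = 0.365 with an estimated correlation). Mitochondrially encoded mRNAs rose instead (11 of 13, median 0.71), including MT-CO1 of complex IV, 2.08-fold, with camera adjusted p = 0.000771 (adjusted p = 0.389 with an estimated correlation). Ribosomal protein genes (34 rose of 50, 35 adjusted over the list alone) included RPL10 (0.37), with camera adjusted p = 0.000341 (adjusted p = 0.122 with an estimated correlation). Their median reversed from 0.15 to -0.06 with library size alone (camera adjusted p = 0.759), which also ended the calls of RPL4 (adjusted p = 0.0998) and RPL5 (0.142).

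**Figure D3:**
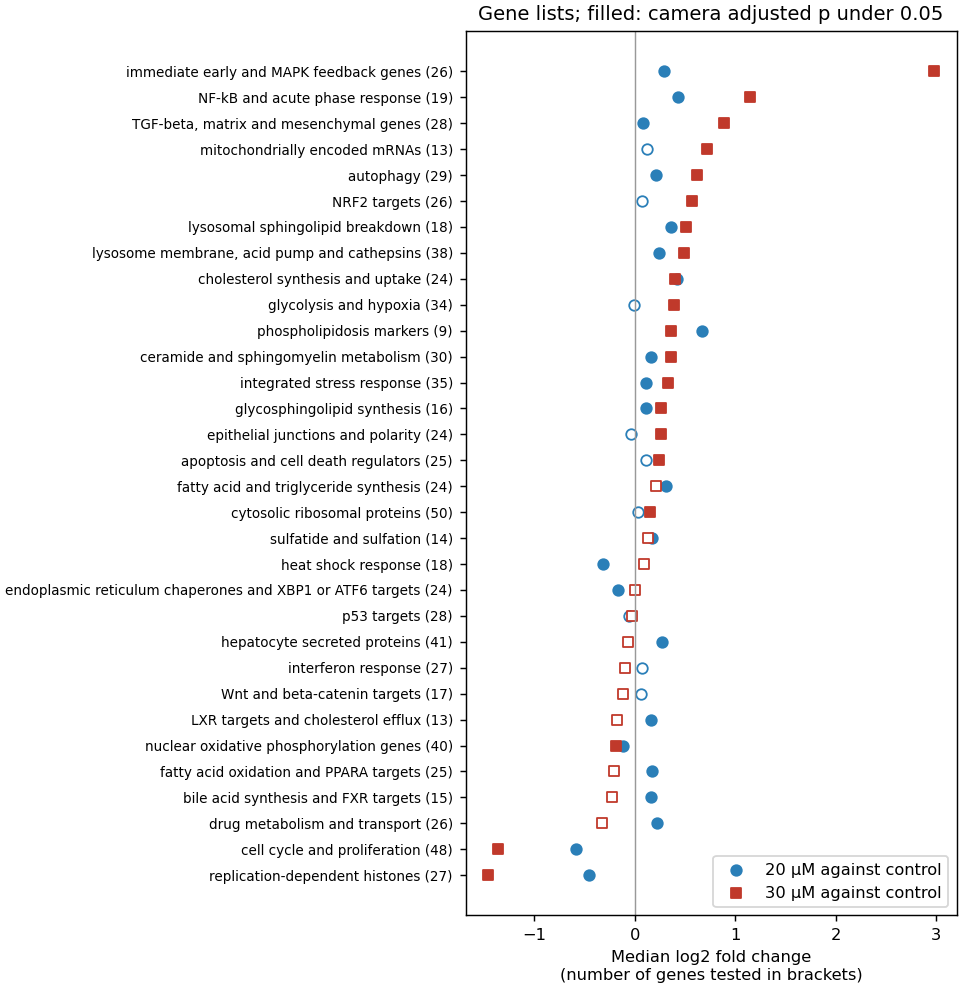
Median log2 fold change (x axis) of the 32 lists (y axis, number of genes tested in brackets), with circles for 20 µM and squares for 30 µM against control, filled where the camera adjusted p was under 0.05. Cell cycle genes went from -0.58 to -1.36 and immediate early genes from 0.29 to 2.98, while the ribosomal list at 30 µM turned from 0.15 to -0.06 with library size alone.

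The remaining 12 lists did not differ at 30 µM against control, though most of their genes changed. Endoplasmic reticulum chaperones split evenly (11 rose and 11 fell of 24, camera adjusted p = 0.683), as did p53 targets (12 and 13 of 28, 0.929, median -0.02 with mean 0.11). Sulfatide genes (6 and 5 of 14, camera adjusted p = 0.671), fatty acid synthesis genes (13 and 9 of 24, 0.25), heat shock genes (9 and 4 of 18, 10 and 4 adjusted over the list alone, 0.263) and LXR targets (5 and 7 of 13, 0.866, median -0.18 with mean 0.16) were mixed. So were fatty acid oxidation genes (6 and 13 of 25, camera adjusted p = 0.162, median -0.21 with mean 0.07), hepatocyte secreted proteins (14 and 19 of 41, 16 and 19 adjusted over the list alone, 0.683) and drug metabolism genes (8 and 14 of 26, 0.671). Bile acid genes (4 and 6 of 15), interferon genes (9 and 12 of 27, 9 and 13 adjusted over the list alone) and Wnt targets (4 and 9 of 17) gave camera adjusted p = 0.280, 0.650 and 0.160. With library size alone the medians turned below 0 for sulfatide (0.14 to -0.07), fatty acid synthesis (0.21 to -0.00), chaperone (0.00 to -0.21) and heat shock genes (0.10 to -0.11).

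Between the doses, 30 µM against 20 µM, the immediate early and MAPK feedback genes rose in full (26 of 26), as did 22 of 26 NRF2 targets with none falling, while all 48 cell cycle genes fell further. CXCL8 rose 28.2-fold (log2 4.82, adjusted p = 1.20e-26) and IGFBP1 16.2-fold (log2 4.02, adjusted p = 1.21e-06), both on top of the rise at 20 µM. Of 41 hepatocyte secreted proteins 25 fell, among them the acute-phase haptoglobin gene HP (-1.11) and the fibrinogen gene FGG (-0.83), and so did 17 of 25 fatty acid oxidation genes. These list calls were lost with an estimated correlation (camera adjusted p = 0.268 and 0.175).

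In total 4942 genes rose and 5099 fell, 57.0% of those tested, 2048 of them by at least 1 log2 unit (914 rose and 1134 fell), and in 9613 of the 10041 genes the groups did not overlap (61.1% of all genes tested). With library size alone the split was 3029 higher and 7690 lower, with upper-quartile factors 4108 and 6067, and with median-ratio factors 5144 and 4854. Other large rises were in IL11, a cytokine of the interleukin-6 family, from 3.02 ± 0.360 to 47.0 ± 1.77 CPM (log2 3.96), DUSP5 (3.91) and AMPD3, an AMP deaminase (3.84). The largest falls were in NFE2 (-2.75), KIRREL2 (-2.74), MAB21L4, an epithelial gene (-2.53), and SCN1A (-2.36).

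Between the doses 20 lists differed, 14 upward and 6 downward. With an estimated correlation 6 of these calls were kept: autophagy (23 rose and 2 fell of 29, median 0.35, camera adjusted p = 2.82e-06), NRF2 targets (median 0.57, 4.31e-09), cell cycle (median -0.82, 1.29e-18) and 3 more. Those were glycolysis and hypoxia (25 and 6 of 34, median 0.35, camera adjusted p = 1.51e-05), NF-kB (13 and 3 of 19, median 0.83, 0.000493) and immediate early genes (median 2.29, 3.88e-15). SQSTM1 (2.03), GCLC (2.04), SLC2A1 (1.79), ICAM1 (1.90), IER3 (3.52) and SPRY4, an inhibitor of MAPK signalling (2.66), rose, while CDC6, which licenses replication origins, fell by 1.13 log2 units. Lysosome genes (24 rose and 5 fell of 38, 24 and 6 adjusted over the list alone, median 0.29, with CTSB at 1.28) gave camera adjusted p = 0.000454 (adjusted p = 0.115 with an estimated correlation). TGF-beta and matrix genes (22 and 3 of 28, median 0.74, with ITGA2 at 2.80) gave camera adjusted p = 1.20e-07 (adjusted p = 0.115 with an estimated correlation).

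Heat shock genes, lower at 20 µM than in controls, rose between the doses (14 and 1 of 18, median 0.43, with the chaperones HSPH1 at 0.74 and HSPA8 at 0.63), with camera adjusted p = 2.86e-05 (adjusted p = 0.115 with an estimated correlation). Endoplasmic reticulum chaperones did the same (16 and 5 of 24, median 0.15, with the co-chaperone DNAJB9 at 0.98), with camera adjusted p = 0.0160 (adjusted p = 0.324 with an estimated correlation, 0.0509 among nuclear protein-coding genes only). With library size alone their median was -0.04 (camera adjusted p = 0.258). Integrated stress response genes (19 and 9 of 35, 20 and 9 adjusted over the list alone, median 0.15, with ATF3 at 2.87) gave camera adjusted p = 0.0149 (adjusted p = 0.203 with an estimated correlation). With library size alone their median was -0.04 (adjusted p = 0.0532). Apoptosis regulators (16 and 4 of 25, 17 and 4 adjusted over the list alone, median 0.23, 0.37 without 20 µM library 1) gave camera adjusted p = 0.00123 (adjusted p = 0.115 with an estimated correlation). Epithelial genes (13 and 6 of 24, median 0.16, with KRT18 at 1.40 and the tight-junction gene CLDN6 at 1.83) gave camera adjusted p = 0.0171 (adjusted p = 0.165 with an estimated correlation). That median was -0.03 with library size alone. Mitochondrially encoded mRNAs (10 rose of 13, 11 adjusted over the list alone, median 0.62) gave camera adjusted p = 0.00101 (adjusted p = 0.324 with an estimated correlation). Ribosomal protein genes (30 rose of 50, median 0.13) gave camera adjusted p = 0.000576 (adjusted p = 0.165 with an estimated correlation). Their median reversed to -0.07 (camera adjusted p = 0.944) with library size alone, where the rises of RPL10 (0.24), RPS13 (0.25), RPL5 (0.22) and RPL4 (0.21) were also lost (adjusted p = 0.177, 0.199, 0.494 and 0.711).

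Of the lists that fell between the doses, histone genes (25 of 27, median -0.98, with H1-5 at -1.49) gave camera adjusted p = 2.53e-10 (adjusted p = 0.115 with an estimated correlation). Fatty acid oxidation genes (4 rose and 17 fell of 25, median -0.33, with the peroxisomal enzyme EHHADH at -1.34) gave camera adjusted p = 0.00679 (adjusted p = 0.175 with an estimated correlation). Hepatocyte secreted proteins (6 rose and 25 fell of 41, median -0.20) gave camera adjusted p = 0.00356 (adjusted p = 0.268 with an estimated correlation). Bile acid genes (2 and 8 of 15, median -0.40, with the reductase AKR1D1 at -1.57 and the bile acid receptor gene NR1H4 at -1.32) gave camera adjusted p = 0.0285 (adjusted p = 0.203 with an estimated correlation, and 0.0801 with library size alone). Wnt targets (3 and 10 of 17, median -0.21, with the receptor TNFRSF19 at -1.29 and the ubiquitin ligase RNF43 at -0.88) gave camera adjusted p = 0.0179 (adjusted p = 0.203 with an estimated correlation). The other 12 lists were not past camera: glycosphingolipid synthesis (7 and 3, adjusted p = 0.0977, but 0.0133 with median 0.40 without a low-count filter), sulfatide (3 and 9, 0.203), ceramide (17 and 6, 0.0977), lysosomal sphingolipid breakdown (7 and 7, 0.516), cholesterol (14 and 7, 0.235), LXR (2 and 6, 0.229) and phospholipidosis (5 and 4, 0.256). Fatty acid synthesis (7 and 13, camera adjusted p = 0.0597) was past it without 20 µM library 1 (0.0377), with library size alone (0.0391), without a low-count filter (0.0454) and among nuclear protein-coding genes only (0.0496). The p53 targets (11 and 12, 11 and 13 adjusted over the list alone, median -0.08 with mean 0.08), drug metabolism (6 and 16, 6 and 17 adjusted over the list alone), nuclear oxidative phosphorylation (4 and 11, 3 and 9 adjusted over the list alone) and interferon genes (5 and 12) gave camera adjusted p = 0.809, 0.0715, 0.243 and 0.243. With library size alone nuclear oxidative phosphorylation was past camera (adjusted p = 0.00725).

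Across both doses, 4108 genes changed against control in the same direction, 2055 upward and 2053 downward, against 895 and 933 if the calls at the doses were independent. These were 68.2% of the genes called at 20 µM, and 2639 of them lay further from control at 30 µM by the test between the doses. Another 757 changed in opposite directions, 394 higher at 20 µM and lower at 30 µM and 363 the reverse. Genes of this kind, all named after their values were seen, were the receptor kinase gene AXL (-0.56 then 2.11), the metallothionein MT2A (-0.84 then 1.04) and KRT18 (-0.41 then 0.99). The reverse order was seen in the endocytic receptor gene CUBN (1.12 then -0.53), the apolipoprotein gene APOA5 (0.46 then -0.98) and the plasma protein gene ITIH1 (0.86 then -0.53). A further 5842 genes changed only at 30 µM and 1155 only at 20 µM.

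Across the 11862 genes called at either dose, which are not independent replicates, the log2 changes correlated with r = 0.606 and a slope of 1.46 for 30 µM on 20 µM. The same 3 controls entered both changes, and in 20 simulated draws of unchanged groups this alone gave r = 0.490 over all genes, against 0.542 in the data. The covariance was 0.182 against 0.0285 in the draws, and the draws held on average 0.15 and at most 2 genes called at both doses in 1 direction. The draws already shared their controls, so the excess in covariance lies beyond sharing at the spread between these libraries. The 3 controls cannot be divided between the doses, so a shared deviation of the controls larger than that spread stays open.

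**Figure D4:**
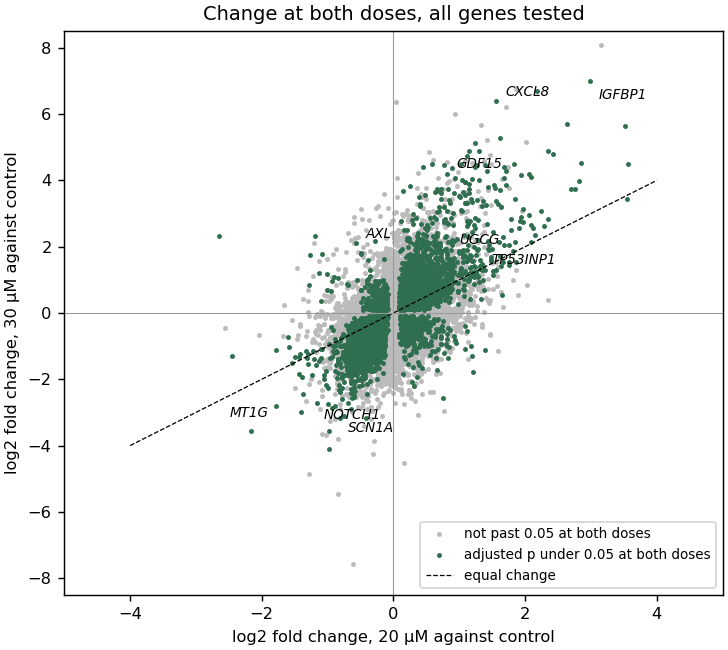
Log2 fold change at 20 µM (x axis) and 30 µM (y axis) against control for the 17623 genes tested, as points, green where the adjusted p was under 0.05 at both doses, with a dashed line of equal change. Of the green points 4108 lie in quadrants of the same direction and 757 in the opposite ones.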

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

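The tests of the hepatocyte list, with their bounds, and the splits of libraries were chosen after the results were seen. Lists that were past camera at 20 µM against control, and past it in the opposite direction between the doses, were picked out as differences between groups: fatty acid oxidation (median log2 -0.33 between the doses), endoplasmic reticulum chaperones (0.15), heat shock genes (0.43), hepatocyte secreted proteins (-0.20) and bile acid genes (-0.40). With an estimated correlation all 5 lost their camera call at 20 µM (adjusted p = 0.245, 0.394, 0.0613, 0.156 and 0.234) and between the doses (0.175, 0.324, 0.115, 0.268 and 0.203). The 394 genes higher at 20 µM and lower at 30 µM than control, and the 363 with the reverse, were picked out for the same reason. All of them also differed between the doses, but calls in opposite directions against the same controls all but ensure that. Records aligned to more than 1 place, which no gene count uses, made up 12.54 ± 0.202% in controls, 14.56 ± 1.12% at 20 µM and 16.84 ± 2.38% at 30 µM (SD, n = 3). In a two-sided exact permutation test, where 0.1 is the smallest value possible, either dose against control gave p = 0.1 and the doses p = 0.3. What these records hold was not analysed here.

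Hepatocyte secreted proteins were past camera upward at 20 µM and downward from 20 to 30 µM, but with an estimated correlation both calls were lost (adjusted p = 0.156 and 0.268), and at 30 µM the list did not differ from control (camera adjusted p = 0.683). The median of the list relative to all genes was 0.126 ± 0.0593 at 20 µM and -0.104 ± 0.0644 at 30 µM (log2, SD, n = 3), a difference of -0.229, and -0.282 over the 32 members outside the 50 most abundant genes. Both values are relative to all genes, and a scaling factor moves all genes of a library nearly alike. They therefore test neither the scaling nor a few abundant genes that took more of the counts. From 20 to 30 µM the list's median log2 change was -0.195 with TMM, -0.175 with median-ratio and -0.272 with upper-quartile factors. It was -0.389 with library size alone. Over the 32 members outside the 50 most abundant genes it was -0.268 with TMM and -0.267 with those 50 genes removed. The fall with every scaling argues against the choice among these scalings as its cause. TMM trims the most abundant genes before it computes a factor, so removing those 50 could hardly move the value and does not test them. At 20 µM the list's median rise was log2 0.268 with TMM. Median-ratio factors, upper-quartile factors and library size alone moved the log2 changes of all genes there by a median of 0.0034, 0.0149 and -0.0163. A factor moves all genes nearly alike, so these small shifts argue against the choice among these scalings as the cause of that rise. The 50 most abundant genes as its cause stay open. A loss of liver-cell expression at the higher dose, untested, stays open, as does whether the list differs from other sets of genes that vary together.

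Each comparison was repeated with its 6 libraries split in every other way into 3 and 3. Only the labelled split, 1 of 10, gave as many genes in each of the 3 comparisons (6020, 10707 and 10041), and the other splits gave 0. The 10 splits are too few for a share under 0.05. The other splits had 231 to 640, 154 to 334 and 177 to 523 genes with an unadjusted p under 0.05 in edgeR.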

How the results depend on the processing

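The numbers of genes past the test, 6020, 10707 and 10041 for 20 µM against control, 30 µM against control and 30 against 20 µM, stayed within 1.5 times of those values under other scalings, filters and tests (DESeq2 5487, 10014 and 9326, limma voom 5924, 10596 and 9916, no low-count filter 5757, 10884 and 9972). With 1 library left out they were 5273 to 5611, 10061 to 10321 and 9276 to 9597, with fewer samples in the fit. They fell to 309, 2822 and 2048 where a change of at least 1 log2 unit was asked for, by that setting's construction. A block for the replicate number gave 5952, 10635 and 9955, but no pairing by number showed across all groups. Deviations from the group mean correlated across genes from -0.202 to 0.352 for same numbers and from -0.256 to 0.343 for others. Between the treated groups alone, same numbers gave 0.152, 0.0767 and 0.352 and others -0.256 to 0.137, so a pairing there stays open. With that block 4069 genes changed in the same direction at both doses, 22, 20 and 20 lists were called, and the bile acid list at 20 µM (adjusted p = 0.0583, camera) and ST3GAL5 (adjusted p = 0.0518, edgeR) lost their calls, and the cause was not tested. Lists called numbered 23, 20 and 20 with camera at correlation 0.01, and 9, 6 and 6 with an estimated correlation. They were 19 to 23, 19 to 20 and 20 to 21 with a library left out, and 27, 30 and 31 with fry, which does not compare a list with other genes. With fry p53 targets at 30 µM (median -0.0220), drug metabolism at 30 µM (-0.32) and p53 targets between the doses (-0.0768) had the opposite direction to camera; the cause was not tested. Genes changed at both doses in 1 direction numbered 3626 to 4072 with a library left out, and the slope over called genes, 1.46, was 1.26 to 1.498, against 1.17 over all genes. Library size alone shifted the median log2 change of all genes by -0.0163, -0.210 and -0.193. The 4 settings added after the data were seen gave 6032, 11552 and 10719 genes with library size alone, 5416, 9932 and 9335 without the 3 libraries that deviate together, 6409, 11041 and 10367 with a covariate for them, and 5986, 10658 and 9991 with the 50 most abundant genes removed. Genes with few counts limit what can be seen: ST3GAL5 at 20 µM had log2 1.02, and 1.54 without those 3 libraries.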

Other observations

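The tests here of immediate early genes, FOXO targets and 3 libraries that deviate together were chosen after those patterns were seen, and the bound for other cells, with the 2 cell types it covers, after the values were seen. Summed CPM of fibroblast markers was 37.4 ± 3.40 in controls, 35.7 ± 0.996 at 20 µM and 24.9 ± 1.40 at 30 µM, nearly all from ACTA2. That of leukocyte markers was 472 ± 23.4, 455 ± 18.8 and 660 ± 16.3, nearly all from LYZ, with no count of PTPRC in any library. Endothelial markers summed to 4.90 ± 0.565, 5.81 ± 0.826 and 4.50 ± 0.470, and cholangiocyte and progenitor markers, mostly SPP1, to 3946 ± 104, 3648 ± 61.4 and 4478 ± 107 (SD, n = 3).

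The 20 µM response joined rises in UGCG (1.83-fold), lysosomal sphingolipid breakdown (16 of 18 genes) and cholesterol synthesis (19 of 24) with a fall in cell cycle genes (44 of 48). At 30 µM the cholesterol and cell cycle lists kept their camera call with an estimated correlation. No explanation of this combination was tested.

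IGFBP1, DEPP1 and KLHL24, all known FOXO targets, were among the 6 largest rises at 20 µM in genes with at least 5 CPM. A list of 26 other FOXO targets was then drawn up from general knowledge, without those 3 genes. At 20 µM 16 of the 23 tested rose and none fell (median log2 0.28, camera p = 3.77e-08, and p = 0.00165 with an estimated correlation), including FBXO32 (3.57), PDK4 (1.82), TXNIP (1.12) and SESN3 (1.12). At 30 µM against control 13 rose and 6 fell, and between the doses 7 rose and 10 fell, and neither was past camera at 0.05. The camera p at 20 µM, not adjusted over lists, goes with the hypothesis of FOXO activity there. The list was drawn up after the 20 µM results were seen, so it is no independent support. A list of targets does not measure FOXO itself, and other regulators of these genes were not tested. SESN3 (-0.16 at 30 µM) and TNFSF10 (0.72 then -0.76) did not follow the dose.

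Immediate early and MAPK feedback genes rose by a median of log2 2.98 at 30 µM, and by 2.95 over the 26 genes after a trend on transcript length and GC content was removed, which argues against that trend as the cause. Of 11 fibroblast and endothelial markers under 1 CPM in controls, 7 were not higher at 30 µM. The median rise of the list, 62.4 CPM, was 28.9 times the highest rise of a marker (PDGFRB, 2.16). This comparison was chosen after the values were seen, so it is no independent test. The small rises argue against these 2 cell types as the cause for the list as a whole only so far as such cells would carry these markers. LYZ (469 to 655 CPM), KRT19 (20.7 to 53.9) and SPP1 (3371 to 3940) rose, but all of them were already present in controls. FCER1G, a leukocyte marker near the floor, rose slightly, and SOX9 (454 to 391) and EPCAM (100 to 93.4) fell. PTPRC and CFTR had no count in any library, and KRT7 had none at 30 µM. Their absence argues against leukocytes and cholangiocytes as the cause only so far as such cells would carry these genes. Progenitors as the cause stay open. Without any 1 library the lowest median was 2.88, which argues against a single library as the source. Sustained MAPK signalling, a stress response at a toxic dose, and handling of the cells at harvest that differed by group are untested and stay open.

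Control 1, 20 µM library 3 and 30 µM library 3 deviated from their groups in the same direction (r across genes 0.331, 0.343 and 0.352). The mean deviation had rho -0.0573 with transcript length across genes, which argues against length as the cause, and rho 0.140 with GC content over 16889 genes, which leaves GC content undecided. Singly the 3 libraries had rho 0.0628, -0.0583 and 0.232 with GC content, and 20 µM library 2, outside the 3, had 0.309. The mitochondrial ribosomal RNAs MT-RNR1 (mean deviation 0.97) and MT-RNR2 (0.91) lay far above the mRNA MT-CO2 (0.25). Processed pseudogenes, chosen after their values were seen, lay at both ends. RPL15P3 (0.91) and RPS7P11 (0.81) were high and RPL23AP42 (-0.39) was low, while the gene RPL15 was at -0.14. Uneven ribosomal depletion could give the deviation of the ribosomal RNAs, and a shared preparation batch could give the whole pattern. Neither was tested, nor was the source of the pseudogene counts, and the labels name no batch.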
